A study of Mus musculus with 16 samples.

How the data were processed

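Stranded total RNA libraries were made from 4 mouse pancreatic tumor lines, each at 2 passages and with or without doxycycline (1000 ng/ml for 24 hours), per the labels' protocols. The passages were 6 and 8 for LGKC4301, 6 and 7 for LGKC4373, 4 and 6 for LGKC4838, and 2 and 4 for LGKC4861. The authors deposited 1 table of whole-number counts per gene for all 16 libraries, not normalised. Reads were aligned to mm10 and counted with STAR and featureCounts, per the submitters' processing notes, which name no versions; the annotation release and the strand setting of the counting are not given in the sources used here. Each column was matched to its sample by name, and no other columns of per-sample values were present. Of 54532 gene IDs, 54495 matched the mouse GENCODE M21 annotation, which gave symbols, biotypes and coordinates, and 37 did not and kept their IDs.

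Totals ran from 32179156 to 77961485 counts. The share of counts from mitochondrial genes was 0.487% to 1.95%, that from small noncoding and ribosomal RNA genes 2.07% to 3.34%, and that of the 10 highest genes 6.20% to 10.1%. A principal component analysis of log2 CPM separated the cell lines on components 1 to 3 (48.3%, 21.9% and 16.9% of the variance) and the treatment on component 4 (4.17%). Reads from near-identical gene copies could have been divided between them by the counting, and values of such genes are uncertain.

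Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 over the 8 line-by-treatment groups (17196 genes), libraries were scaled by TMM, and robust quasi-likelihood models were fitted. The doxycycline effect across lines came from a model with cell line and treatment (11 residual degrees of freedom), which leaves differences in response between lines in the residual spread. The effect in each line, the difference between lines (an F test of 3 interaction terms) and the differences between untreated lines (an F test) came from a model with 8 group means (8 residual degrees of freedom). Genes were called at a Benjamini-Hochberg adjusted p of 0.05. Unless stated otherwise, levels are TMM-normalised CPM (counts scaled to library size), with SD over 4 line means or over 2 passages.

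Before the data were examined, 32 gene lists were fixed: cAMP-PKA-CREB targets, G protein and cAMP machinery, glycolysis, TCA cycle, nuclear-encoded oxidative phosphorylation, mitochondrially encoded mRNAs, pentose phosphate pathway, hypoxia targets, gastric, mucin, intestinal, ductal, acinar and endocrine genes, fibroblast, immune and endothelial markers, epithelial junction genes, mesenchymal transition genes, classical transcription factors, basal-like keratins, KRAS-MAPK output, YAP-TAZ targets, proliferation, unfolded protein response, ATF4 stress, sterol and fatty acid synthesis, interferon-stimulated, NF-kB and chemokine, WNT target, TGF-beta target and small noncoding RNA genes. The 29 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 on log2 CPM (prior count 2), again with an estimated correlation, and with fry, each adjusted over the lists. At the preset correlation 8 lists passed and with an estimated correlation 0 did (2 at an unadjusted p under 0.05). The p of fry, which asks if a list's genes move on balance in one direction, passed for 9 lists, and its mixed p, which asks if they change in either direction, for 22. The response of each list's mean was compared between lines with limma.

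Genes were named by a rule fixed at the same time. It takes Gnas and Kras, the 10 largest rises and 10 largest falls across lines with a mean log2 CPM of at least 1 and one direction in all 4 lines, and up to 4 members of each list with the lowest p. It also takes the 8 genes of the same level with the lowest interaction p, the 4 largest rises and 4 largest falls in each line, and up to 3 members of each lineage list that differed most clearly between untreated lines. Gm20721, Mal2, Itgb3, Snap25, Plau, Kit, Kcne2, Wfdc1, Bdnf, Nfil3, Pdx1, Hnf1a, Mdh2, Irf7 and Stat1 fall outside it or complete a small count, and were chosen after their values were seen.

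The steps were tested on simulated counts with the real means and library sizes and 200 changed genes. Across lines the model called 89.6% of genes changed 1.5-fold and 100% of those changed 2-fold or 4-fold, with 7 unchanged genes called among 17196. In LGKC4301 it called 67.2%, 89.6% and 98.5% at 1.5-fold, 2-fold and 4-fold, and for the difference between lines 23.9%, 83.6% and 98.5%. For untreated lines, with the line means made equal, it called 70.1%, 94.0% and 100%. Camera and fry found a planted list of 20 genes and called 0 of 29 others. The across-line changes were planted alike in every line, with only the spread between passages added, and changed genes were drawn from well-counted genes. These rates therefore do not cover real differences in response between lines or genes of low count. The simulated genes varied independently, so this cannot test the preset correlation. In the real lists the estimated correlation reached 0.805, for ATF4 stress genes.

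The alternatives were other scalings (DESeq2 size factors and upper quartile), DESeq2 1.42.0 and limma-voom in place of edgeR, no low-count filter or a filter of 1 CPM in 8 libraries, and exclusion of mitochondrial, ribosomal RNA and small noncoding genes. Others were a 1.5-fold minimum, an adjusted p of 0.01, models without the line term or with line and passage as a block, passages summed or taken singly, and leaving out each library or line. Thinning all libraries to the smallest total was added after the data were seen. The set tests of the lists take the libraries as replicates. They were not run with passages summed or taken singly, without the line term, without single libraries, or by DESeq2 or limma-voom. Their ranges over the alternatives leave these settings out.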

Results

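RNA was sequenced from 4 mouse pancreatic tumor cell lines, LGKC4301, LGKC4373, LGKC4838 and LGKC4861. All 4 carried a Cre driver expressed from the pancreatic p48 locus, a Cre-activated Kras G12D allele, the reverse tetracycline transactivator at Rosa26 and a tetracycline-responsive GNAS R201C transgene. GNAS encodes the stimulatory G protein alpha subunit, which activates adenylyl cyclase to make cAMP. Each line was sampled at 2 passages without doxycycline and at the same 2 passages after 24 hours in 1000 ng/ml doxycycline, giving 16 libraries in 8 groups of 2. Library totals ran from 32179156 to 77961485 counts (median 36382434.5), and the deepest 3 libraries, at 68645506 to 77961485, were all from LGKC4861, whose untreated passage 2 library held 36623069. Unless stated otherwise, levels are given as TMM-normalised CPM, counts scaled to library size. The 2 passages of each group differed by more than sampling noise (chi-square per degree of freedom 14.3 to 32.5), so none was treated as a duplicate. No line without the transgene was treated with doxycycline, so each value below measures the drug and the transgene together. The p-values within lines measure the spread between passages, which may be technical, and those across lines also the differences in response between lines.

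The first question was whether doxycycline raised Gnas. Gnas (ENSMUSG00000027523, chromosome 2, 174284320 to 174346744, mm10) rose in every line and at both passages, from 712 ± 173 to 2823 ± 848 CPM (SD, n = 4 line means). The log2 fold change was 1.98 ± 0.12 (SE; edgeR adjusted p = 7.29e-08). The fold was 4.20 in LGKC4301, 2.69 in LGKC4373, 5.78 in LGKC4838 and 3.68 in LGKC4861, and these responses differed between lines (edgeR interaction adjusted p = 0.000216). Reads of the transgene may have been counted in this gene, so the value is not the endogenous transcript alone. Gm20721, a gene model within the Gnas interval, also rose, with a log2 fold change of 2.46 ± 0.16 (SE), and its reads and those of Gnas are uncertain because the strand setting of the counting is not given in the sources used here. Kras (ENSMUSG00000030265, chromosome 6, 145216699 to 145250239) had a log2 fold change of 0.14 ± 0.07 across lines (SE; edgeR adjusted p = 0.201). Within LGKC4301 it rose by 0.47 ± 0.11 (SE; edgeR adjusted p = 0.0273), against -0.03, 0.12 and -0.01 in LGKC4373, LGKC4838 and LGKC4861, and this difference between lines did not pass (edgeR interaction adjusted p = 0.0977).

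**Figure D1:**
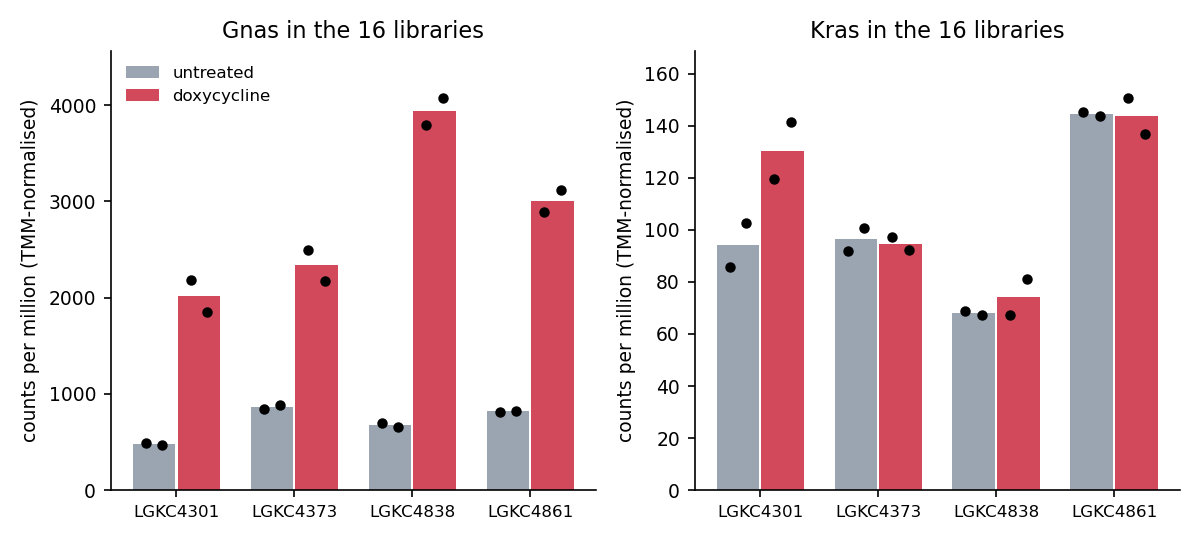
TMM-normalised CPM (vertical axes) of Gnas (left) and Kras (right) in each cell line (horizontal axes), without and with doxycycline; points are the 2 passages and bars their mean. Every doxycycline library lies above every untreated library for Gnas, with line folds of 2.69 to 5.78.

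Among genes with a mean log2 CPM of at least 1 and one direction in all 4 lines, those with the largest rises were of several kinds. Mucl3, a mucin-like protein gene, rose from 6.37 ± 5.14 to 385 ± 371 CPM (SD, n = 4 lines), a log2 fold change of 5.57 ± 0.60 (SE; edgeR adjusted p = 6.53e-05). Il33, an alarmin cytokine, rose from 36.5 ± 14.1 to 906 ± 433 CPM, a log2 fold change of 4.61 ± 0.35 (SE; edgeR adjusted p = 3.32e-06). Gkn1, a secreted protein of gastric surface mucous cells, rose by 4.43 ± 0.35 log2 units (SE), from 1.28 ± 1.34 to 32.1 ± 41.6 CPM. Its response did not differ detectably between lines (edgeR interaction adjusted p = 0.847). In LGKC4373 it was near the floor, at 0.0454 and 0.550 CPM, and its change of 3.55 ± 1.93 log2 units there did not pass (SE; edgeR adjusted p = 0.321). Cftr, a chloride channel of ductal epithelium activated by protein kinase A, rose by 3.48 ± 0.49 log2 units (SE), from 13.2 ± 9.71 to 272 ± 397 CPM.

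The other large rises were Akap12, a protein kinase A anchoring protein (log2 fold change 4.63), Ramp3, a receptor activity-modifying protein (4.27), Cd55, a complement regulator (3.78), and the transcription factors Sox17 (3.09) and Rorb (3.03), with Serpinb9b at 3.05. The largest falls under the same rule were Megf10 at -2.33, the anion transporter Slc26a9 at -2.21, the cytokine Csf2 at -1.95, and Prex2, a Rac exchange factor, at -1.94. Next were Pgf at -1.85, Ccbe1 at -1.80, Fgf2 at -1.79, the hyaluronan synthase Has3 at -1.77, the metalloprotease Adam12 at -1.75 and Klhl1 at -1.68. Adam12 went from 18.4 ± 17.9 to 5.53 ± 5.91 CPM (SD, n = 4 lines). All 20 genes passed the edgeR test and moved in one direction in all 4 lines, which was part of the rule that chose them. Genes outside the rule had larger fitted changes. Among them were the rises of Kit (log2 fold change 8.39), Kcne2 (7.72) and Wfdc1 (5.83), which were also called with passages summed. Fabp1, of lower level, had a larger fitted fall, which rests on LGKC4838.

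**Figure D2:**
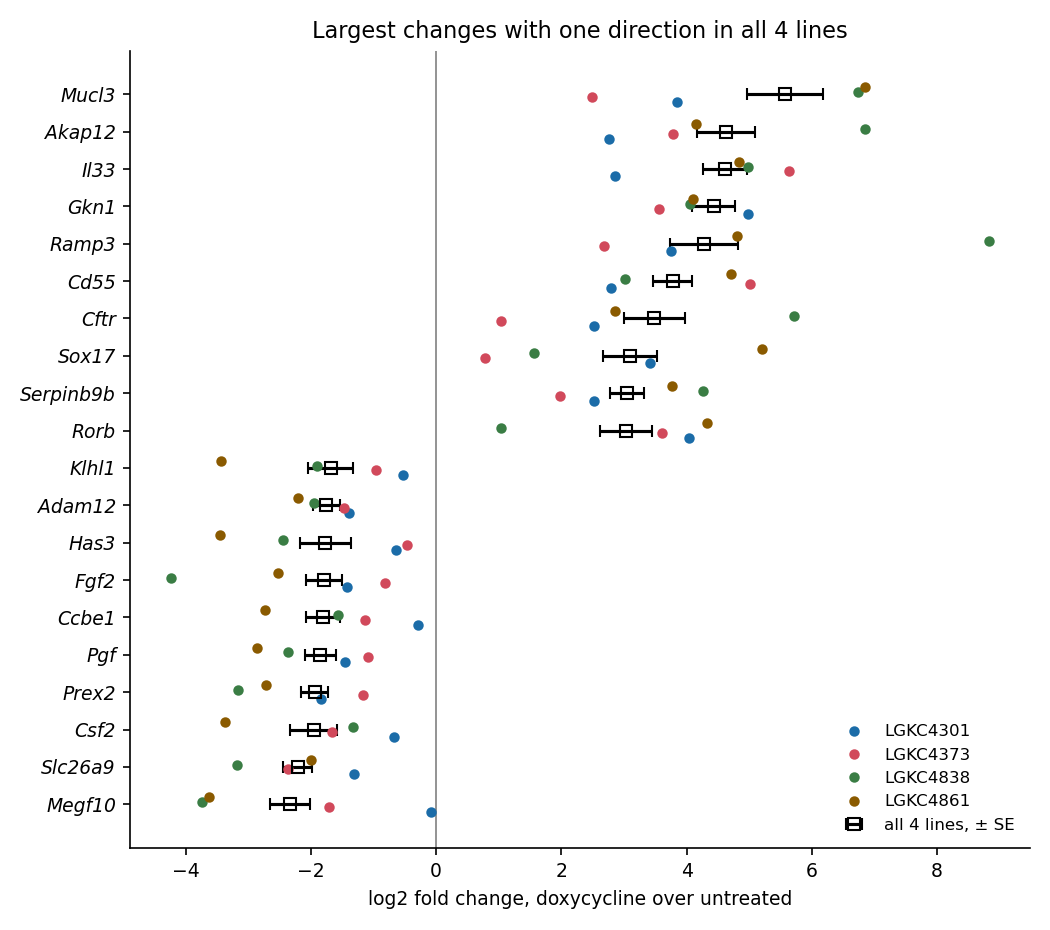
Log2 fold change with doxycycline (horizontal axis) of the 20 genes with the largest changes (vertical axis) among those with a mean log2 CPM of at least 1 and one direction in all 4 lines. Squares are the estimate across lines with its standard error and coloured points the estimate in each line; Mucl3 is highest at 5.57 and Megf10 lowest at -2.33.

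In all, 3625 of 17196 genes passed an edgeR adjusted p of 0.05, of which 1979 rose and 1646 fell. A change beyond 2-fold was seen for 593 of the risen and 201 of the fallen genes, and the median size of the log2 change was 0.52 for risen and 0.32 for fallen genes. Of the 3625 genes, 80.7% moved in one direction in all 4 lines, a share raised by the choice itself, since the model favours genes that respond alike in the lines. This count rests on the 16 libraries as replicates: with the 2 passages summed, so that the line is the replicate, 38 genes passed (33 up and 5 down), and of the 20 genes above only Gkn1 and Adam12 did. Those 38 genes also included Gnas, Sik1, Mal2, Itgb3, Snap25, Plau and Cdh5, and without a cell line term 40 genes passed, while without LGKC4861 2028 passed.

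Genes known to be induced through cAMP, protein kinase A and CREB rose on balance. Of the 25 tested members of this list, 13 rose and 2 fell, and adjusted over the list alone the counts were 14 and 2 (camera adjusted p = 5.69e-07; adjusted p = 0.212 with an estimated correlation, 2.36e-10 to 0.212 over the alternatives). Sik1, a salt-inducible kinase, rose from 19.5 ± 5.26 to 80.7 ± 25.8 CPM (SD, n = 4 lines), a log2 fold change of 2.02 ± 0.08 (SE; edgeR adjusted p = 4.91e-10). The phosphodiesterase gene Pde4d rose by 1.56 ± 0.11, the nuclear receptor gene Nr4a2 by 1.88 ± 0.14 and Crem, a cAMP-responsive modulator, by 1.13 ± 0.10 log2 units (SE). Bdnf at -0.75 and Nfil3 at -0.48 were the members that fell across lines. Within lines by edgeR, 10 rose and 0 fell in LGKC4301 (1 fell by DESeq2) and 11 rose and 1 fell in LGKC4373. In LGKC4838 15 rose and 2 fell, and in LGKC4861 13 rose and 5 fell. In the list of G protein, adenylyl cyclase, protein kinase A and EPAC genes, 6 of 24 rose and 2 fell, and adjusted over the list alone 6 rose and 3 fell. Gnas, the induced gene, was among the risen members and enters the list's mean and tests. Adcy9 rose by 0.69 and the regulatory subunit Prkar1a by 0.37, while the kinase inhibitor Pkig changed by -0.33. The list median was -0.04, its mean 0.16, and its test upward and not past the threshold (camera adjusted p = 0.706).

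Hypoxia-inducible factor targets and glycolytic genes were also higher. Of 18 hypoxia genes, 9 rose and 0 fell, and adjusted over the list alone 12 rose (camera adjusted p = 6.52e-06; adjusted p = 0.475 with an estimated correlation, 1.81e-08 to 0.475 over the alternatives). Ndrg1 rose by 1.04 ± 0.13, the angiogenic factor Vegfa by 0.94 ± 0.13, Bhlhe40 by 0.49 ± 0.08 and Bnip3, a mitophagy receptor, by 0.86 ± 0.20 log2 units (SE). Of 24 glycolysis genes, 9 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.00594; adjusted p = 0.728 with an estimated correlation, 0.000228 to 0.728 over the alternatives). The kinases Pgk1, Pfkfb2 and Pfkl rose by 0.46, 0.52 and 0.37, and the member that fell was Slc16a1, a lactate transporter, at -0.58 ± 0.07 log2 units (SE). Both lists responded differently between lines (limma adjusted p of the list mean 0.000956 for hypoxia and 0.0135 for glycolysis). In LGKC4861 16 of 18 hypoxia genes and 17 of 24 glycolysis genes rose, and in LGKC4301 0 rose in either by edgeR, DESeq2 or limma-voom (4 and 3 at an unadjusted edgeR p under 0.05).

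Mucin, gastric and ductal genes moved in part. Of 18 mucin and mucin secretion genes, 8 rose and 0 fell by edgeR, and adjusted over the list alone 9 rose (camera adjusted p = 0.0116, and adjusted p = 0.475 with an estimated correlation, 0.00132 to 0.475 over the alternatives). By limma-voom 2 fell, by DESeq2 0 did, and 1 fell at an unadjusted edgeR p under 0.05. By line 7 rose and 4 fell in LGKC4838 and 7 rose and 1 fell in LGKC4861, and 0 rose or fell in LGKC4301 and LGKC4373 by edgeR (limma adjusted p of the list mean 0.0268). Those zeros were 3 and 2 rises at an unadjusted edgeR p under 0.05, and 1 and 0 by DESeq2 and by limma-voom. Spdef, a transcription factor of mucus-secreting cells, rose from 0.0441 ± 0.0627 to 3.91 ± 7.61 CPM (SD, n = 4 lines). This rests on LGKC4838, from 0.133 to 15.3 CPM, while LGKC4861 reached 0.257 and LGKC4301 and LGKC4373 0.0146 and 0.0512 (edgeR interaction adjusted p = 0.0297). The glycosyltransferase genes Galnt6 and Gcnt1 rose by 2.08 and 0.85 log2 units, and Creb3l4 by 0.96. Of 16 gastric genes, 5 rose and 2 fell, and adjusted over the list alone 6 rose and 2 fell (camera adjusted p = 0.151). Gkn2 rose by 4.39 and Gkn3 by 2.26, while Anxa10 changed by -0.68. Of 14 ductal genes, 7 rose and 3 fell, and adjusted over the list alone 7 rose and 4 fell (camera adjusted p = 0.151). The carbonic anhydrase gene Car2 rose by 1.69 ± 0.23 and Hnf1b by 0.38 ± 0.07, and the progenitor factor Sox9 changed by -0.64 ± 0.11 log2 units (SE).

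Among transcription factors of the classical pancreatic cancer subtype, 6 of 12 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0478; adjusted p = 0.475 with an estimated correlation, 0.00332 to 0.475 over the alternatives). Gata6 rose by 0.62 ± 0.07, Foxa3 by 1.19 ± 0.16, Elf3 by 0.63 ± 0.11 and Klf5 by 0.50 ± 0.10 log2 units (SE), and Pdx1 and Hnf1a changed by -0.31 and -0.29. Of 24 sterol and fatty acid synthesis genes, 2 rose and 6 fell, and adjusted over the list alone 2 rose and 8 fell (camera downward, adjusted p = 0.0101; adjusted p = 0.729 with an estimated correlation, 0.000312 to 0.729 over the alternatives). Dhcr24, Pcsk9 and Sc5d changed by -0.27, -0.62 and -0.29, and the LDL receptor gene Ldlr rose by 0.21. Of 12 epithelial junction genes, Esrp2, a splicing regulator, was the one that rose, by 0.70 ± 0.07 log2 units (SE), also adjusted over the list alone (camera adjusted p = 0.316). Of 15 mesenchymal transition genes, Vim at -0.47 and Lox at -0.56 fell and 0 rose by edgeR, also adjusted over the list alone (camera adjusted p = 0.168). By DESeq2 0 rose and by limma-voom 1 did.

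Of 12 intestinal genes, Cdhr5 rose by 1.01 and Fabp1, a fatty acid binding protein, changed by -3.79 ± 0.55 log2 units (SE), and adjusted over the list alone 1 rose and 2 fell (camera adjusted p = 0.706). The Fabp1 change rests on LGKC4838, without which it was 0.60 (edgeR adjusted p = 0.776, and 1.24e-29 to 1.00 over the alternatives), and it was -1.40 by DESeq2 and -0.72 as the mean of the within-line contrasts. Of 7 basal-like keratin genes, Krt15 rose by 0.80, and adjusted over the list alone 0 did (camera adjusted p = 0.193). Of 25 proliferation genes 0 rose and 0 fell by edgeR, also adjusted over the list alone (camera adjusted p = 0.262). At an unadjusted p under 0.05 0 rose and 3 fell, by DESeq2 1 fell and by limma-voom 0 did, with Mki67 at -0.16 ± 0.07 log2 units (SE). Within lines 7 fell in LGKC4373 (8 by DESeq2 and by limma-voom), 1 fell in LGKC4861 and 2 rose in LGKC4838, and the list mean did not differ detectably between lines (limma adjusted p = 0.231). Of 22 KRAS-MAPK output genes, Ier3 rose by 0.55 and Emp1 and Spred2 changed by -0.36 and -0.18, with the same counts adjusted over the list alone (camera adjusted p = 0.851). Of 19 YAP-TAZ targets 5 rose and 3 fell, and adjusted over the list alone 6 rose and 3 fell (camera adjusted p = 0.629), with Wwc1 at 0.66, Amotl2 at 0.40, Axl at -0.40 and Myof at -0.45.

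Of 13 TGF-beta targets, Smad6 rose by 0.42 and Ltbp2 and Ski changed by -1.21 and -0.20, and adjusted over the list alone 1 rose and 3 fell (camera adjusted p = 0.796). Of 8 WNT targets, Apcdd1 rose by 0.59, Rnf43 by 0.28, and Tcf7 changed by -0.62. Adjusted over the list alone 2 rose and 2 fell, and the median was 0.06, the mean -0.24 and the test downward (camera adjusted p = 0.893). Of 17 NF-kB and chemokine genes, Cxcl3 rose by 1.26 and Csf2 changed by -1.95, the same 1 and 1 adjusted over the list alone, with a median of -0.12, a mean of 0.02 and a downward test (camera adjusted p = 0.706). Of 15 unfolded protein response genes, Edem1 and Dnajb9 rose by 0.27 each and Creld2 changed by -0.23, and adjusted over the list alone 3 rose and 1 fell (camera adjusted p = 0.479). Of 20 ATF4 and mitochondrial stress genes, Vldlr rose by 0.81, also adjusted over the list alone (camera adjusted p = 0.358). In LGKC4373 that list had a median of 1.21, with 5 members up by edgeR, 13 by DESeq2 and 4 by limma-voom, against medians of -0.34, 0.19 and -0.40 in LGKC4301, LGKC4838 and LGKC4861 (limma adjusted p of the list mean between lines 0.0654).

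No mitochondrial list passed the camera test. Over all tested genes, the share past the edgeR threshold was 21.1%. Of 21 nuclear-encoded oxidative phosphorylation genes and of 10 mitochondrially encoded mRNAs 0 rose and 0 fell by edgeR, also adjusted over the list alone, with medians of -0.03 and 0.14 (camera adjusted p = 0.479 and 0.440). At an unadjusted p under 0.05 1 of the first fell and 1 of the second rose, by DESeq2 0 of either passed, and by limma-voom 0 and 1. Of 20 TCA cycle and pyruvate dehydrogenase genes, Ogdh rose by 0.17, Mdh2 by 0.17 and Pdha1 by 0.15, and Idh3a and Sdhb changed by -0.22 and -0.16, with the same counts adjusted over the list alone (camera adjusted p = 0.851; fry mixed adjusted p = 7.41e-08, for change in either direction). Of 7 pentose phosphate genes, Rpe rose by 0.14 and Rpia and Pgls changed by -0.30 and -0.16, the same 1 and 2 adjusted over the list alone. That list had a median of 0.04, a mean of -0.01 and a downward test (camera adjusted p = 0.875). Of 11 small noncoding and RNA quality genes, Neat1 rose by 0.61 and Snhg1 and Gas5 changed by -0.28 and -0.17, the same 1 and 2 adjusted over the list alone. Its median was 0.04 and its mean -0.14, and camera pointed down (adjusted p = 0.953) while fry pointed up (adjusted p = 0.951).

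Of 6 tested endothelial markers, Cdh5, Tek and Esam rose, to 2.37 ± 3.29, 1.74 ± 2.71 and 2.07 ± 2.27 CPM (SD, n = 4 lines), and Flt1 changed by -0.76 log2 units. Adjusted over the list alone 4 rose and 1 fell (camera adjusted p = 0.0478; adjusted p = 0.475 with an estimated correlation, 0.00332 to 0.475 over the alternatives), and with only genes of at least 1 CPM in 8 libraries the list pointed down (camera adjusted p = 0.404). Of 3 immune markers, Cd68 rose by 0.96 and Cd14 changed by -0.60, also adjusted over the list alone. Of 9 fibroblast markers, Col6a3 changed by -1.20, and adjusted over the list alone 1 rose and 1 fell (camera adjusted p = 0.851). The 2 acinar genes (Cela1 at 0.37 and Bhlha15 at 0.12) and the 2 endocrine genes (Syp at -0.74 and Pax6 at 0.09) did not pass over all genes by edgeR, while adjusted over the list alone 1 acinar gene rose and 1 endocrine gene fell. By DESeq2 and by limma-voom 1 acinar gene rose over all genes, and 0 endocrine genes passed.

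The list calls rest in part on single lines, the filter and the tool. The set tests were not run with the line as the replicate, the setting that lowered the count of genes most. Without LGKC4861 the camera adjusted p was 0.194 for glycolysis and 0.205 for classical transcription factors, without LGKC4838 0.197 for interferon-stimulated, 0.219 for sterol and 0.210 for endothelial genes, without LGKC4373 0.0903 for sterol genes, and without LGKC4301 0.0526 for classical transcription factors and 0.153 for endothelial markers. With line and passage as a replicate block the camera adjusted p was 0.0587 for classical transcription factors and 0.067 for endothelial markers. With only genes of at least 1 CPM in 8 libraries it was 0.065 for mucins and 0.0747 for classical transcription factors, and with thinned libraries 0.0589 for endothelial markers. By fry, which makes no comparison with other genes, the adjusted p was 0.0502 for glycolysis and for interferon-stimulated genes and 0.0605 for sterol genes. Calls were gained by fry for the G protein and cAMP machinery (adjusted p = 0.0459, range over the alternatives 0.0459 to 0.909), epithelial junction (0.0459, range 0.0459 to 0.729), ductal (0.0459) and basal-like keratin genes (0.0345). The first of these lists includes Gnas itself. With camera, calls were gained without LGKC4373 for gastric (0.0186, range over the alternatives 0.0186 to 0.737) and ductal genes (0.0475, range 0.0459 to 0.737), without LGKC4838 for lower proliferation genes (0.00998, range 0.00998 to 0.908), and without LGKC4861 for ATF4 stress (0.0300, range 0.0300 to 0.908) and basal-like keratin genes (0.0300, range 0.0300 to 0.477).

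The next question was whether the response differed between lines. It did for 2422 genes (edgeR interaction F test; 4724 with line and passage as a replicate block), 841 of them among the 3625 genes called across lines, and 396 genes rose in one line and fell in another. Sgk1, a serum- and glucocorticoid-regulated kinase gene, had a log2 fold change of 5.20 ± 0.16 in LGKC4838 against 0.45 ± 0.13, 0.55 ± 0.12 and 1.24 ± 0.12 in LGKC4301, LGKC4373 and LGKC4861 (SE; edgeR interaction adjusted p = 1.92e-09). Tnc, an extracellular matrix gene, was at 3.83 ± 0.21 in LGKC4838 and -2.28 ± 0.16 in LGKC4861, and Apol9a at 5.20 ± 0.27 and -2.98 ± 0.27 (SE). The leptin receptor gene Lepr (4.60) and Enpp3 (5.81) rose in LGKC4838 against -0.32 and -0.04 in LGKC4861, and Gimd1 changed by -3.03 in LGKC4838 against 0.13. Timp3, a metalloprotease inhibitor gene, rose by 3.85 ± 0.16 in LGKC4861 and changed by -1.03 ± 0.14 in LGKC4373, and Sox17 rose by 5.20 in LGKC4861 and 1.56 in LGKC4838 (SE).

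Interferon-stimulated genes had the lowest p of the tested list means for this difference (limma adjusted p = 1.82e-05). In LGKC4838 17 of 18 rose, among them Irf7 from 5.50 to 67.7 and Stat1 from 3.66 to 18.5 CPM, against 0, 2 and 3 members in LGKC4301, LGKC4373 and LGKC4861. The 0 in LGKC4301 was 2 at an unadjusted edgeR p under 0.05, 1 by DESeq2 and 0 by limma-voom. Across lines 9 rose and 1 fell, and adjusted over the list alone 14 rose and 1 fell (camera adjusted p = 0.00029; adjusted p = 0.728 with an estimated correlation, 3.44e-06 to 0.728 over the alternatives). Stat2 rose by 0.60, Mx1 by 2.28 and Oas2 by 4.08, and the member that fell was Ifit2 at -0.59 log2 units. The mean of 14 of the 29 tested lists responded differently between lines. In LGKC4838 13 of 24 sterol and fatty acid synthesis genes and in LGKC4373 8 fell, against 2 in LGKC4861 and 0 in LGKC4301 (1 at an unadjusted edgeR p under 0.05, 0 by DESeq2 and by limma-voom; limma adjusted p of the list mean 0.00365).

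**Figure D3:**
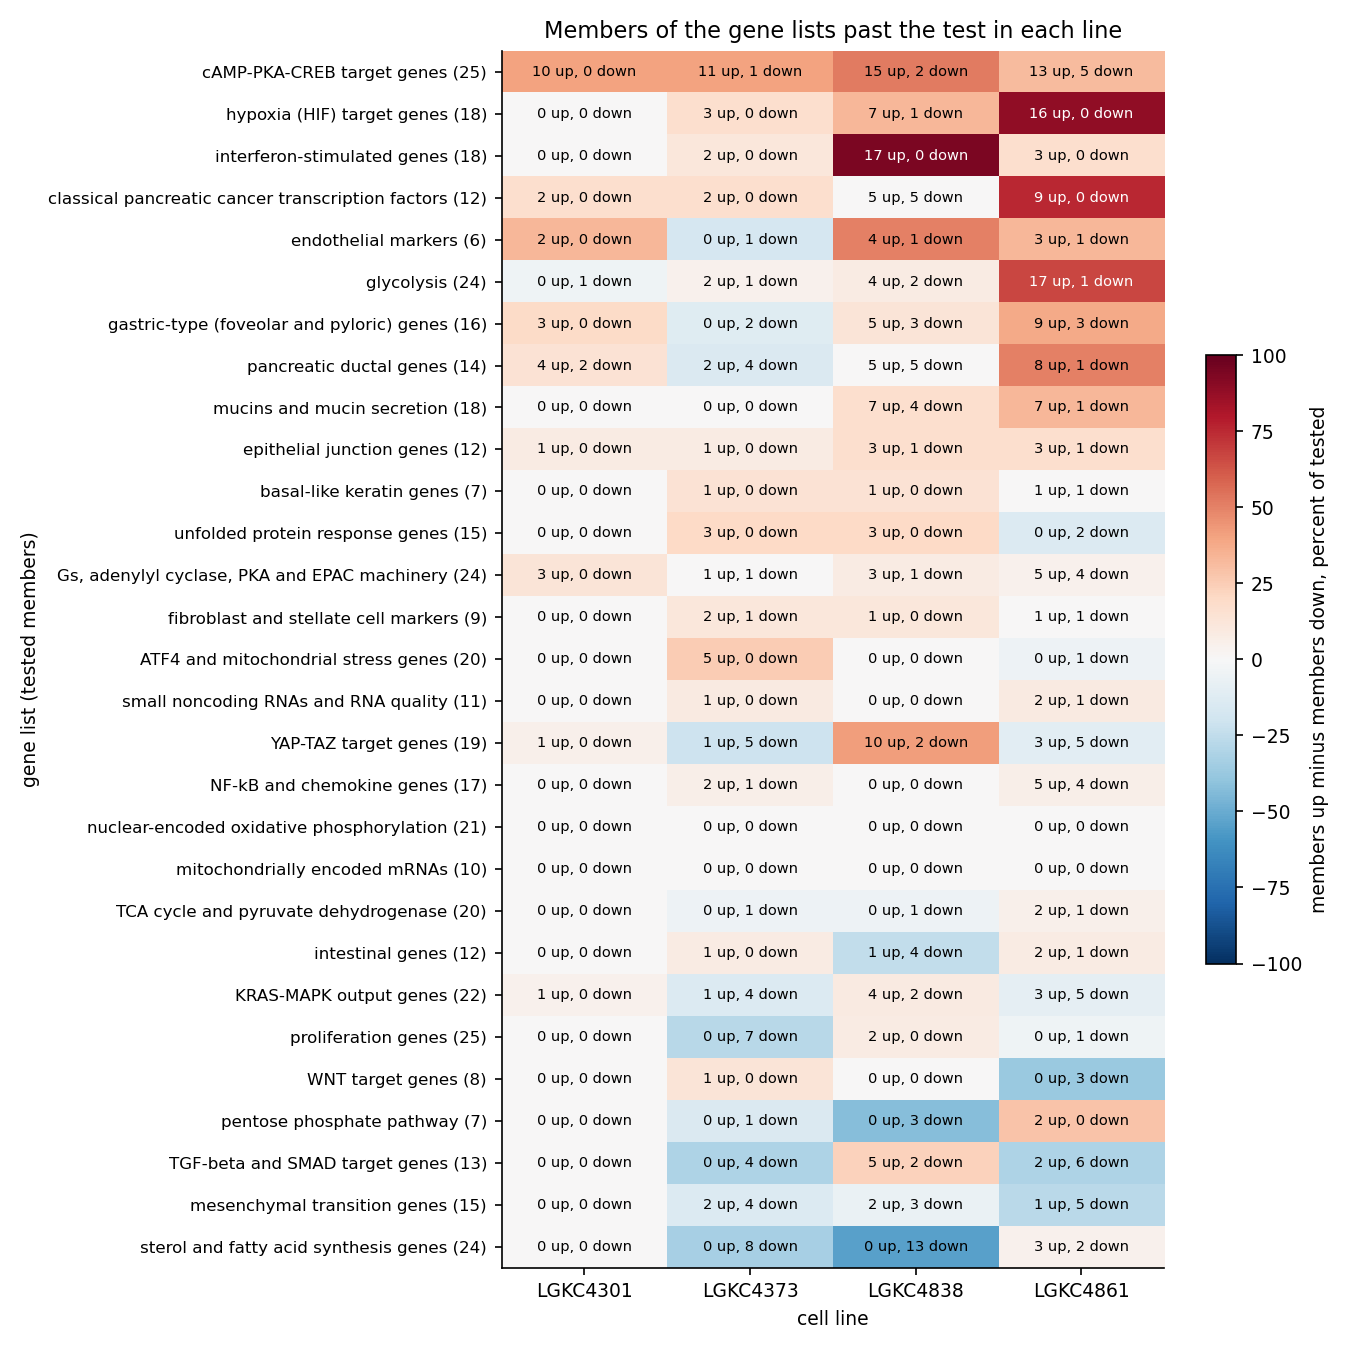
Members of each gene list (vertical axis, tested members in brackets) past an edgeR adjusted p of 0.05 in each cell line (horizontal axis). Colour gives members up minus members down as a percent of those tested; 17 of 18 interferon-stimulated genes rose in LGKC4838, and 16 of 18 hypoxia genes rose in LGKC4861.

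Within single lines, the gastric gene Gkn1 led in LGKC4301, from 2.84 ± 2.38 to 90.7 ± 56.3 CPM (SD, n = 2), followed by the activin antagonist Fst (log2 fold change 4.43), Rorb (4.04) and Slc44a3 (3.90), while Prex2, Pgf, Calcrl and Slc26a9 changed by -1.84, -1.46, -1.35 and -1.31. In LGKC4373 the receptor gene Klrc1 rose by 6.33 and Il33 by 5.64, Cxcl5 went from 0.0751 to 3.38 CPM and Cd55 rose by 5.02, while Atp1b1, Rasl11b, Tnip3 and Camk2b changed by -3.84, -3.73, -3.49 and -3.26. In LGKC4838 Ramp3 rose from 0.107 ± 0.076 to 49.7 ± 11.9 CPM (SD, n = 2), Akap12 by 6.84, Mucl3 by 6.74 and Arhgap8 by 5.87. There Sprr1a and Megf10 changed by -4.10 and -3.74, and Cd34 and Fgf2 went from 0.333 and 0.787 to 0.0133 and 0.0395 CPM. In LGKC4861 Mucl3 rose by 6.84, the integrin gene Itga7 by 5.67, the aldehyde dehydrogenase gene Aldh3a1 by 5.24 and Sox17 by 5.20, while Slc14a1, Megf10, Has3 and the hyaluronan synthase gene Has2 changed by -4.23, -3.62, -3.45 and -3.44.

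The number of genes past an edgeR adjusted p of 0.05 was 440 in LGKC4301 (369 up and 71 down), 1851 in LGKC4373 (961 and 890), 2816 in LGKC4838 (1534 and 1282) and 3493 in LGKC4861 (2057 and 1436). All 4 lines shared 113 risen genes, against 0.22 for independent lists, and 28 fallen genes, against 0.0229. The lists come from the same fit, with a spread and a level per gene that the lines share in part. Independence was therefore not to be expected, and the excess does not measure how alike the responses were. Across genes, which are not independent replicates, the log2 fold changes of pairs of lines correlated at 0.184 to 0.302. With 2 passages per arm these counts move with single libraries: LGKC4301 had 200 genes without untreated passage 8 and 229 without doxycycline passage 6, and 740 by DESeq2 and 1081 with no low-count filter, while LGKC4373 had 889 and 869 without untreated passages 6 and 7 and 1178 without doxycycline passage 6. LGKC4838 had 1729 genes without untreated passage 4 and 1662 without doxycycline passage 6, and LGKC4861 2106 without untreated passage 4 and 2307 without doxycycline passage 4. With line and passage as a replicate block the counts were 1716, 3598, 4365 and 5382 in LGKC4301, LGKC4373, LGKC4838 and LGKC4861.

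**Figure D4:**
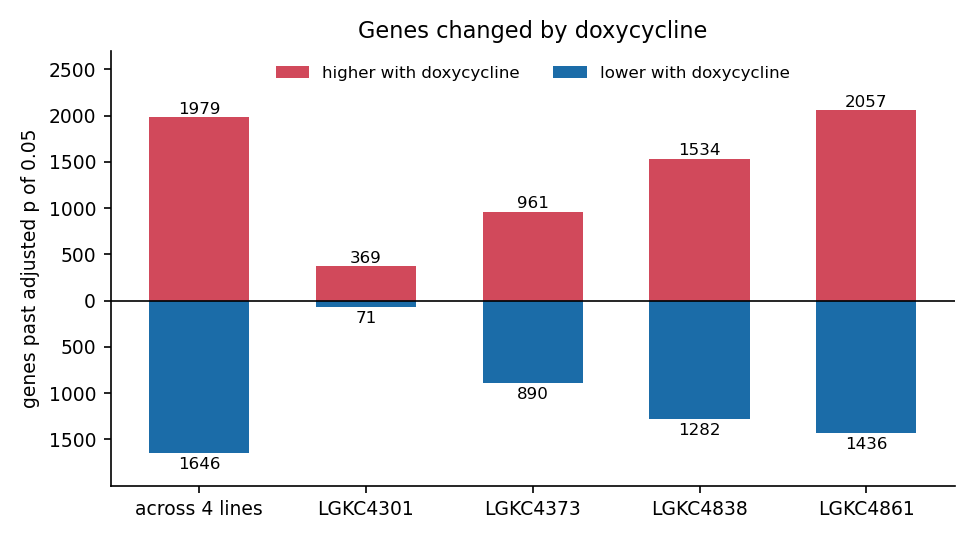
Genes past an edgeR adjusted p of 0.05 (vertical axis), higher (above 0) or lower (below 0) with doxycycline, across the 4 lines and in each line (horizontal axis). LGKC4301 has the lowest count, 369 up and 71 down, and LGKC4861 the highest of the single lines, 2057 up and 1436 down.

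The untreated lines differed among themselves at 14346 genes, 83.4% of those tested (edgeR F test), with LGKC4373 apart on epithelial and mesenchymal genes. Cdh1, the E-cadherin gene, was at 25.3 ± 3.36 CPM in LGKC4373 and at 810 ± 69.2, 687 ± 25.8 and 518 ± 14.5 in LGKC4301, LGKC4838 and LGKC4861 (SD, n = 2; edgeR adjusted p = 7.73e-14). Hnf4a, a transcription factor of endodermal epithelium, was at 0.810 ± 0.0309 in LGKC4373 and at 214 to 394 in the others, and Krt7 at 93.6 ± 12.9 against 1022 to 1517. Matrix genes were the reverse, with Sparc at 721 ± 7.09 and Fbn1 at 121 ± 11.1 in LGKC4373 against at most 5.29 and 0.327 elsewhere, and Col1a2 at 1026 ± 63.0 against at most 0.977 CPM. The mean log2 CPM of the mesenchymal list was 6.45 in LGKC4373 against 1.74 to 3.88 elsewhere, and that of the fibroblast list 3.98 against -3.51 to -1.91.

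Single gastric and intestinal genes differed among the other lines, not all in one order. Cldn18, a gastric claudin gene, was at 554 ± 47.2 in LGKC4838 and 827 ± 4.96 in LGKC4861 but at 2.24 ± 0.224 in LGKC4301 and 0.492 ± 0.206 in LGKC4373 (SD, n = 2), and Aqp5 was highest in LGKC4838 at 826 ± 35.4. Anxa10, also a gastric gene, was highest in LGKC4301 at 384 ± 21.1, against 68.7 ± 8.08 in LGKC4838 and 83.2 ± 0.093 in LGKC4861. The intestinal genes Krt20 and Cdh17 were at 266 ± 29.1 and 738 ± 57.8 in LGKC4301 and 225 ± 5.86 and 943 ± 75.7 in LGKC4838, against 40.7 ± 3.81 and 211 ± 0.327 in LGKC4861 and 0.373 ± 0.0965 and 3.23 ± 0.646 in LGKC4373. Cdx2 was highest in LGKC4838 at 81.6 ± 12.9, as was the mucin glycosyltransferase gene Galnt4 at 468 ± 10.3, and Agr2, a gene of secretory cells, was at 13.3 ± 0.085 there and under 0.1 elsewhere. Line and any handling batch were not separable in this comparison, and passage numbers overlapped between lines only in part (passage 6 in LGKC4301, LGKC4373 and LGKC4838, passage 4 in LGKC4838 and LGKC4861).

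**Figure D5:**
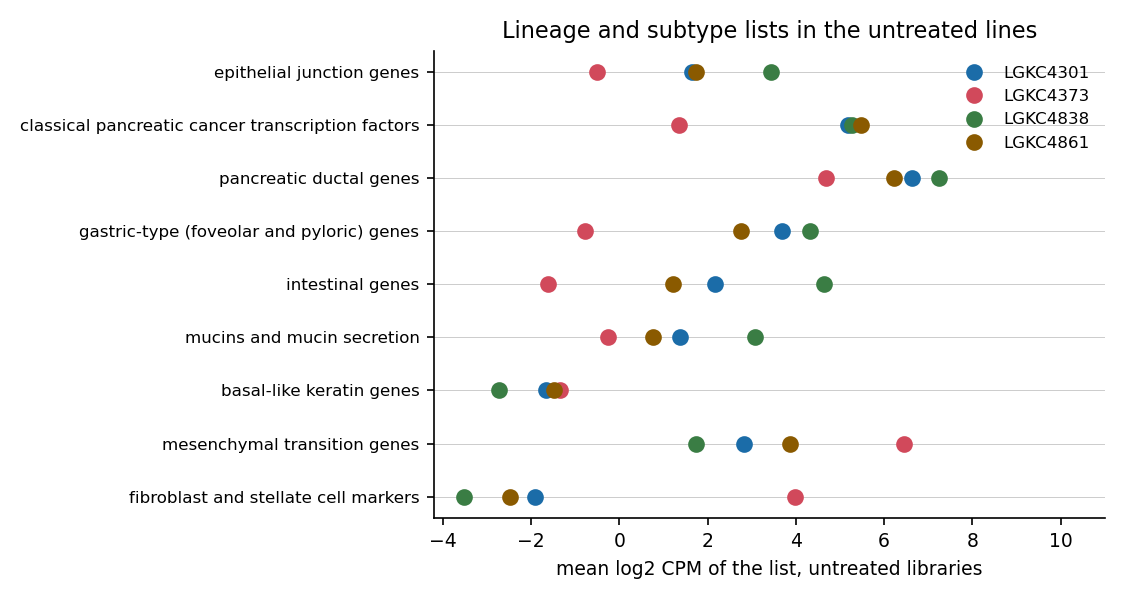
Mean log2 CPM (horizontal axis) of the lineage and subtype lists (vertical axis) in the untreated libraries of each line, 1 point per line. LGKC4373 is highest on the mesenchymal list at 6.45 and lowest on the epithelial junction and classical transcription factor lists.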

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

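The tests of library depth, of immune cell markers and of interferon transcripts were chosen only after the results they concern were seen. In 100 random regroupings within the lines, of 648 possible, 1 gave as many genes as the real split, the real one itself, with 3625 genes against at most 872 in the others. This argues against a random division of the libraries as the source of the count. Mixed regroupings leave the doxycycline effect in the residual spread, which lowers their counts. They also take libraries and not lines as the unit, so they do not bear on the drop with passages summed.

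The doxycycline effect differed between lines for 2422 genes, and Gnas was among them (edgeR interaction adjusted p = 0.000216). Of the 20 genes with the largest changes across lines, 18 also differed in size between lines. Among the rises the edgeR interaction adjusted p was 0.0139 for Mucl3, 0.000901 for Akap12, 7.52e-06 for Il33, 0.000145 for Ramp3, 0.000333 for Cd55, 7.17e-07 for Cftr, 6.43e-08 for Sox17, 3.63e-07 for Serpinb9b and 1.22e-05 for Rorb. Among the falls it was 4.81e-05 for Megf10, 0.0066 for Slc26a9, 0.0154 for Csf2, 0.000325 for Prex2, 0.000592 for Pgf, 0.000281 for Ccbe1, 0.000165 for Fgf2, 0.00133 for Has3 and 0.00457 for Klhl1. For the genes chosen by this test it was 1.92e-09 for Sgk1, 9.74e-09 for Tnc, 1.21e-08 for Lepr, Apol9a and Timp3 each, 2.67e-08 for Enpp3 and 5.91e-08 for Gimd1.

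The mean of 14 lists responded differently between lines. The limma adjusted p was 0.00365 for cAMP-PKA-CREB targets and for sterol and fatty acid synthesis, 0.0135 for glycolysis, 0.000956 for hypoxia targets, 0.00444 for gastric genes, 0.0134 for intestinal genes and 0.0108 for ductal genes. It was 0.0268 for mucins, classical transcription factors and TGF-beta targets, 0.000363 for endothelial markers and basal-like keratins, 0.0346 for the unfolded protein response and 1.82e-05 for interferon-stimulated genes.

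LGKC4301 had 440 changed genes, against 1851 to 3493 in the other lines. Depth was not the whole cause, since with all libraries thinned to one total the lowest other line still had 4.08 times as many genes, and a spread borrowed from the other lines was not, since with each line fitted alone LGKC4301 had 144 genes and the lowest other line 14.7 times as many. With line and passage as a replicate block the counts were 1716 in LGKC4301 and 3598 in the lowest other line, so how far apart the lines stand depends on how the passages are modelled. Whether the response of LGKC4301 was smaller cannot be told from slopes of log2 fold changes on the mean of the other lines. Its slope was 0.489 (95% bootstrap interval over genes 0.44 to 0.537). The LGKC4373 slope was 0.468 and its interval overlapped, and LGKC4838 and LGKC4861 had 0.651 and 0.911. Each slope used its own genes, from 2028 to 3409 of them, and its own set of other lines, so the slopes share no common scale. The median difference between passages was largest in LGKC4301 (0.185 log2 units against 0.138 to 0.174), so a wider spread between its passages stays open. A difference between the lines themselves also stays open, as untested.

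Interferon-stimulated genes rose in LGKC4838 far more than elsewhere. A single passage did not decide this, since the list median was 2.74 log2 units at passage 4 and 2.92 at passage 6. Immune cells as the source of the whole rise were argued against, since 8 of 12 immune markers, among them those of T cells and B cells and the macrophage markers Csf1r and Adgre1, were at 0 in all 4 libraries of this line. Ptprc, the general leukocyte marker, was at 2.35 and 1.03 CPM with doxycycline against 2.66 and 1.80 without. The CPM of immune markers and interferon genes here are per raw library total, not TMM-normalised. The sum of all 12 markers was lower with doxycycline (lowest doxycycline minus highest untreated -96.0 CPM), but Cd14 sets that sum. Without Cd14 the same difference was 6.25 CPM, which Cd68, a macrophage marker, sets (15.4 or more against 7.53 or less), so a small contribution cannot be told apart from none. Whether interferon transcripts rose cannot be told apart from no change at these counts, with a lowest-over-highest ratio of 1.34 from 8 and 0 counts untreated and 11 and 20 with doxycycline, all of Ifne, and 0 of Ifnb1. A response of this line to the induction or to the drug may account for the pattern, as a hypothesis that no test here separates.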

How the results depend on the processing

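Thinning the libraries was chosen only after the results were seen; all other alternatives were fixed beforehand. The 3625 genes across lines became 38 with passages summed (3334 at an unadjusted p under 0.05), 80 with first passages alone, 79 with second passages alone, 40 with no cell line term, 2028 without LGKC4861, 1321 with a 1.5-fold minimum and 1844 at an adjusted p of 0.01. The first 3 and the fit without LGKC4861 have fewer samples by construction, and the last 2 a stricter threshold. Without a cell line term, the differences between lines stay in the residual spread. Leaving out each other line gave 2667 to 3409 genes, and why LGKC4861 weighs more was not tested. Of the genes in both single-passage fits (42), 30 were among the 38. LGKC4301 had 740 genes by DESeq2 and 1081 with no low-count filter, and the cause was not tested. Thinned to the smallest total, 3507 genes passed across lines and 455 in LGKC4301.

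Leaving out single libraries gave 2825 to 3712 genes across lines, 200 to 487 in LGKC4301, 869 to 1939 in LGKC4373, 1662 to 2902 in LGKC4838, 2106 to 3573 in LGKC4861, 1789 to 2512 for the difference between lines and 13658 to 14361 for untreated lines. Where 1 library of a group remained, it was assumed to vary like the other groups.

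Untreated and doxycycline libraries of a line share passage numbers, but their deviations correlated at 0.265, 0.148, 0.115 and 0.0435, so not in every line above 0.1, and the passages were taken to share only a number. With line and passage as a replicate block, 3204 genes passed across lines, 1716 in LGKC4301, 3598 in LGKC4373, 4365 in LGKC4838, 5382 in LGKC4861 and 4724 for the difference between lines, and 6 lists passed, without classical transcription factors and endothelial markers.

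Of the 8 lists, 5 passed under the stricter filter, which tests fewer genes, and 0 with an estimated correlation (2 at an unadjusted p under 0.05). The endothelial list turned downward under the stricter filter (camera adjusted p = 0.404, over the alternatives 0.00332 to 0.475), and Fabp1 turned upward without LGKC4838 (log2 fold change 0.60, edgeR adjusted p = 0.776, over the alternatives 1.24e-29 to 1.00); the cause was not tested. Over the alternatives run for them, the lists stayed on the same side of the threshold in 342 cases, lost the call in 24 and gained it in 9. Changes of direction where neither fit passed are among these 342, such as that of the small noncoding list by fry. Many of the 342 are lists called in neither fit, and only the 8 called lists could lose a call. The 141 named genes, some of them not called to begin with, stayed on the same side in 4309 cases, lost the call in 609 and gained it in 124. There too, changes of direction where neither fit passed were not counted. The mean Gnas fold over lines was 4.09, 4.10 with raw totals and 3.52 to 4.55 without single lines. DESeq2 gave no adjusted p for 1334 of the genes across lines, which count as neither kept nor lost. No scaling moved the median of all genes by over 0.1.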

Other observations

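The tests of the Pde symbol family and of the chromosome 4 scan with long noncoding genes were chosen only after results were seen, as was every gene and symbol family named here. Genes with a Pde symbol, most of which encode phosphodiesterases that break down cyclic nucleotides, moved apart. The set was taken by symbol and also holds genes such as Pde4dip and Pde6d that do not encode such enzymes. Of 17 tested, Pde4b rose by 3.79 ± 0.34, Pde8a by 3.09 ± 0.36, Pde3b by 1.46 ± 0.15 and Pde7a by 0.25 ± 0.05 log2 units (SE), along with Pde4d and Pde10a. Pde5a changed by -0.39 ± 0.09 and Pde9a by -0.61 ± 0.18. The idea that genes with this symbol rise together was not borne out (camera adjusted p = 0.166 over symbol families of at least 8 genes). This does not test the enzymes alone.

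Among other families defined by symbol, Serpinb protease inhibitor genes rose (7 up and 1 down of 11, median log2 fold change 1.64; camera adjusted p = 0.00026; adjusted p = 0.64 with an estimated correlation) and so did Ugt glucuronosyltransferase genes (4 up of 13, median 0.90; camera adjusted p = 0.00229, and adjusted p = 0.64 with an estimated correlation). Histone genes with Hist symbols were lower (10 of 63 down, median -0.35; camera adjusted p = 7.28e-07, and adjusted p = 0.813 with an estimated correlation). Ribosomal protein genes were slightly lower, with medians of -0.13 for Rpl (9 of 49 down) and -0.13 for Rps (7 down and 2 up of 44), and adjusted p = 0.813 and 0.816 with an estimated correlation. Of genes with Utp, Nop and Rrp symbols 5 of 10, 5 of 8 and 5 of 8 were lower, as were 7 of 21 Nup nuclear pore genes, while Nol genes did not pass (1 up and 5 down of 10; camera adjusted p = 0.166), and none of these passed with an estimated correlation (adjusted p = 0.64, 0.64, 0.675 and 0.813 for Utp, Nop, Rrp and Nup). Mitochondrial Mrps (6 of 29 down), Mrpl (8 down and 1 up of 48) and Tomm genes (4 of 9 down) had camera adjusted p = 0.00518, 0.0138 and 0.0186, and adjusted p = 0.761, 0.829 and 0.64 with an estimated correlation. Several of these families share near-identical sequences, so counts of single members are uncertain.

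Ighv1-62, annotated as an immunoglobulin variable pseudogene (chromosome 12, 115371986 to 115372433, mm10), had 0 counts in each of the 8 untreated libraries and 5 to 20 counts in each of the 8 doxycycline libraries. No other gene showed this pattern. Which sequence these reads came from was not tested.

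On chromosome 4, neighbouring genes were silent in some lines. Cdkn2a and Cdkn2b, which encode cell cycle inhibitors, had 0 counts in LGKC4301 and LGKC4373, and in LGKC4861 0 apart from 2 Cdkn2b counts with doxycycline, while LGKC4838 had 75 and 538 untreated and 72 and 395 with doxycycline. Mtap, next to them, was at 44.1 and 11.4 CPM in LGKC4838 and LGKC4301 and at 0.0208 and 0.0397 in LGKC4373 and LGKC4861, and Klhl9 was at 0.107 in LGKC4861 against 129 to 170 elsewhere. These CPM, and those of the scans below, are per raw total, with untreated and doxycycline libraries of a line pooled. A first scan, of protein-coding genes silent in a line and at 2 CPM or more in another, did not single out the locus: its longest run there was 2 genes, and 1000 of 1000 shuffles gave a run as long. A second scan, with settings chosen after that result, added long noncoding genes and lowered the level to 1 CPM. It found runs of 7 genes in LGKC4861 and 6 in LGKC4373, and 0 of 1000 shuffles gave a run as long, although a Hoxa run of 8 genes in LGKC4301 and LGKC4861 was longer. A loss of this segment in some lines may be the source, as a hypothesis only, since RNA does not measure copy number and silencing would look alike.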
